A study of Drosophila melanogaster with 4 samples.

How the data were processed

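Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h, with an antibody against histone H4 monomethylated at lysine 20 (H4K20me1). The 4 samples were 2 ChIP replicates and 2 input controls, the inputs being DNA from the same kind of chromatin without immunoprecipitation. Each input was paired with 1 replicate's list per the labels. Lists of regions were analysed for the 2 ChIP replicates and for the replicate set as a whole, giving 3 lists, and the latter is called the combined list. The input libraries entered only through the lists, and no list of their own was analysed here. The labels number the replicates without saying whether they came from separate embryo collections, so the spread between them may be technical.

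Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Each list holds regions of significant enrichment on FlyBase release 5 of the genome, per the file headers. The region caller, its threshold, its window and the way the replicates were combined are not given in the sources used here. Every region carries 1 score deposited by the authors, and its definition is not given in the sources used here. The scale of that score was settled from the values. Scores of pairs of regions differed exactly, within 1e-09, by the base-2 logarithm of 2/1, 3/2, 4/3 or 5/4 in 1227 pairs of the replicate 1 list, 1180 of replicate 2 and 638 of the combined list. At the natural or base-10 logarithms of those ratios there were 0 such pairs in each list. Differences of exactly 2, which is also the base-2 logarithm of 4/1, occurred in 37, 21 and 13 pairs, and differences equal to the other 3 ratios themselves in 0. The score was therefore read as a log2 ratio, so that a score of 1 stands for a doubling. What the ratio is taken over, and how each library was scaled, was left open, so scores were used to describe, rank and filter regions within a list, and were set side by side between lists only for overlapping regions. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it was computed. Weak regions are the ones most exposed to that limit, since whether they pass a caller's threshold depends on the number of reads.

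Lengths of the 14 sequences were taken from the file headers. These were the large chromosome arms 2L, 2R, 3L, 3R and X, chromosome 4, the heterochromatic sequences 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and the unplaced sequences U and Uextra, together 169 Mb. Coverage was the percentage of the bases of a sequence that lie inside regions, in each replicate, in both replicates at once, or in the combined list. A region counted as shared when at least 1 base overlapped a region of the other replicate. Regions of 20 kb or more were called wide. The 1 region of depletion in the combined list was kept out of all coverage values.

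Overlap of the replicates was measured as the Jaccard index, the bases in both lists divided by the bases in either, and compared with 1000 circular shifts of replicate 2 within each sequence (one-sided). Scores were compared across reciprocal best overlapping pairs of regions. These correlations run across regions, which are not independent replicates, and carry no p-value. Coverage of X was compared with that of 2L, 2R, 3L and 3R over 500 kb windows by a two-sided permutation test with 100000 resamples. A window at the end of an arm was kept if it reached 50% of the full length. Windows of 1 genome are not replicates, so this p-value compares positions within these libraries. Neighbouring windows also depend on one another, which a rotation of the 5 joined arms in steps of 10 kb, with 10000 rotations, takes into account. The 10 pairs of large arms were compared in the same way, with Benjamini-Hochberg adjustment over the 10 pairs, and also by rotation of each joined pair, comparisons chosen after seeing the data. So were the comparisons of X with the autosomes for regions of score 1.5 or more and for wide regions.

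The comparisons, tests and most alternatives were fixed before the data were examined. The alternatives were a median-score filter, merging of regions less than 1 kb apart, a reciprocal overlap of 50%, windows of 100 kb and 1 Mb, rotation, the combined list, and leaving out each replicate. Regions named individually were the 5 widest and the 5 of highest score in the combined list, also fixed beforehand. Other positions, such as the longest stretches without a region and the strong regions of 1 replicate, were chosen after their values were seen. Planned comparisons with genes, gene features and gene lists were not run. The gene table at hand describes Release 6 of the genome, whereas the regions lie on release 5, and coordinates were not converted, so positions are given without the genes they hold.

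Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The methods were tested on simulated data. Of 40 simulated independent lists, each a circular shift of replicate 1 within the large arms, 2 were called as overlapping replicate 1 at 0.05. The overlap test itself uses circular shifts, so this checks its calculation only. Over 238 windows, the comparison of X with autosomes made a call in 7 of 100 simulations without a difference. With X lower by 6 percentage points it made a call in 82 of 100. These window values were drawn independently from the autosomal windows, so the rates do not cover the dependence of neighbouring windows.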

Results

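The genomic distribution of H4K20me1, a histone mark placed by the methyltransferase PR-Set7, was profiled by ChIP-seq in wild-type Drosophila embryos aged 14 to 16 h. The data comprised 2 ChIP replicates, each with its input control, and the regions called as enriched in each replicate and in the replicate set (the combined list). Depth is unknown, because the lists hold no read counts. Positions are on FlyBase release 5.

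Regions enriched for H4K20me1 lay on all 5 large arms and on chromosome 4. Replicate 1 held 6022 regions spanning 32.4 Mb, and replicate 2 held 5991 regions spanning 32.98 Mb. Together they averaged 32.7 Mb ± 0.440 (SD, n = 2), and they covered 27.0% ± 0.355 (SD, n = 2) of the 5 large arms and chromosome 4. Most regions were short and a minority was very wide. The median width was 3081 bp in replicate 1 and 3102 bp in replicate 2, while the widest regions reached 116737 and 118274 bp. Wide regions, of 20 kb or more, numbered 231 in replicate 1 and 235 in replicate 2 and held 23.6% and 24.2% of the covered bases. Of the covered bases, 50% lay in the 946 widest regions of replicate 1 and the 924 widest of replicate 2.

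Wider regions also had higher scores. Whether the score averages over a region or records its highest value is unknown. In replicate 1 the median score, a log2 ratio, was 0.49 in regions under 2 kb, 0.79 at 2 to 5 kb, 1.17 at 5 to 10 kb, 1.43 at 10 to 20 kb and 1.51 above 20 kb. Replicate 2 gave 0.49, 0.77, 1.15, 1.34 and 1.49 in the same classes. Across regions, Spearman's correlation of score with width was 0.823 in replicate 1, 0.814 in replicate 2 and 0.804 in the combined list.

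The same parts of the genome were marked in both replicates. Of the 35.3 Mb covered in either list, 30.1 Mb was covered in both, a Jaccard index of 85.2%. Shifted lists gave 15.8% on average and at most 21.4% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). A region of the other replicate overlapped 5469 (90.8%) of the regions of replicate 1 and 5301 (88.5%) of those of replicate 2. All 231 wide regions of replicate 1 and all 235 of replicate 2 were among them. Sharing needed only 1 base, and the lists held 49.5 and 49.2 regions per Mb of the 5 large arms. Wide regions would therefore touch a region of the other list in many positions. The share given by position alone was not computed.

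Regions found in 1 replicate alone were narrow and weak. The 553 regions private to replicate 1 had a median score of 0.52 and a median width of 1602 bp, against 0.84 and 3384 bp for its shared regions. The 690 private to replicate 2 had a median score of 0.53 and a median width of 1638 bp, against 0.84 and 3518 bp. Below a score of 0.5, 72.5% of replicate 1 regions and 67.5% of replicate 2 regions were shared. Between 1 and 1.5 the shares were 100% and 99.3%. Regions of higher score were also wider, so part of this rise may come from width alone, which was not tested.

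A few strong regions were nevertheless seen once. Replicate 1 had 5 private regions with a score of 1 or more, of which 3 lay on the unplaced sequence U, 1 on 2RHet and 1 near the centromere end of 2R, from 251731 to 253045 (score 2.73). Replicate 2 had 12, of which 7 lay on U, 1 on YHet from 299860 to 301927 (score 2.26) and 4 on the large arms, all 4 with scores of 1.09 or less.

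Enrichment levels of matched regions were similar in both replicates. Over 4985 reciprocal best pairs, scores of the replicates had a Pearson correlation of 0.952 and a Spearman correlation of 0.923. The median absolute difference was 0.09, and 90% of pairs lay within 0.24. Replicate 1 had the higher score in 54.1% of pairs, with a median difference of 0.02.

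**Figure D1:**
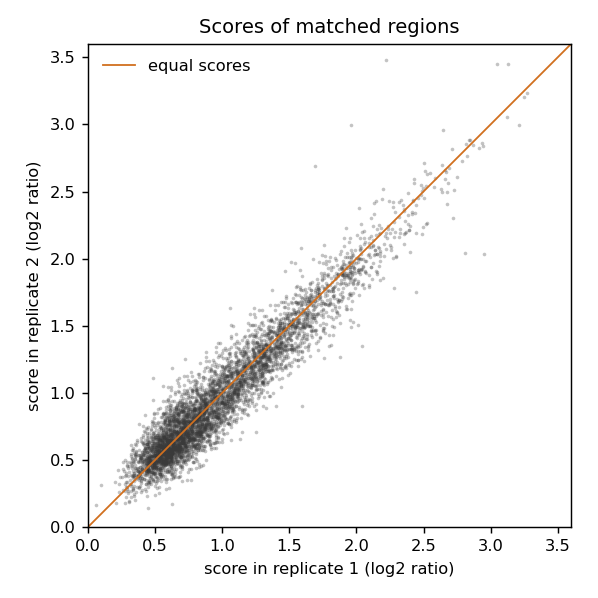
Score (log2 ratio) of each matched region in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with 1 point for each of the 4985 reciprocal best pairs and a line at equal scores. Points follow the line over the whole range, with a median absolute difference of 0.09.

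The combined list extended the marked territory. It held 6850 enriched regions over 37.8 Mb, 31.2% of the 5 large arms and chromosome 4. It contained nearly all bases marked in both replicates (99.99%), and 79.5% of its own bases were marked in both. Another 2.80 Mb was marked in neither replicate's list. Of its regions, 4634 (67.6%) touched regions of both replicates and had a median score of 0.80. The 1140 that touched 1 replicate and the 1076 that touched neither were weaker, with medians of 0.37 and 0.36, and the latter were only 1295.5 bp wide at the median. No test was made, since the combined list rests on the same libraries.

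The only depleted region of the 3 lists was on 2R from 11566356 to 11568030, in the combined list, with a score of -0.02. It lay 2787 bp from the nearest enriched region on one side and 2292 bp on the other.

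The share of its length that was marked varied from arm to arm by more than the spread between replicates. Arm 2R was marked most, at 32.0% ± 0.611 (SD, n = 2), followed by 3R at 28.8% ± 0.418 and 3L at 26.9% ± 0.0921. Arm 2L stood at 25.2% ± 0.630 and X at 22.5% ± 0.0755. Chromosome 4, the small and largely heterochromatic autosome, was marked over 16.3% ± 0.188 and had no wide region in any of the 3 lists. In both replicates the arms fell in the same order, 2R, 3R, 3L, 2L, X and 4.

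Over 500 kb windows, 3 of the 10 pairs of large arms differed after Benjamini-Hochberg adjustment and 4 did before it. Arm 2R exceeded X by 9.44 percentage points (adjusted permutation p = 0.00300) and 3R exceeded X by 6.39 (adjusted permutation p = 0.0289). The difference of 2L from 2R was -6.62 percentage points (adjusted permutation p = 0.0472). These calls treat neighbouring windows as exchangeable. By rotation of each joined pair of arms, 0 of the 10 pairs differed, with or without adjustment (lowest permutation p = 0.0938, adjusted 0.632). Such rotations include small shifts that leave both arms nearly in place, so they can miss a difference. Even the largest gap, 2R against X, had permutation p = 0.279 by rotation. The lack of a call therefore does not show that arms are alike. Stretches of the large arms as long as chromosome 4 were marked over 25.5% at the median in both replicates, against 14.3% for chromosome 4. Of 1124 such stretches, taken every 100 kb, 93 (8.27%) were marked as little, so chromosome 4 was within the range of the large arms.

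Sequences assigned to heterochromatin or left unplaced were almost free of called regions. The 6 heterochromatic sequences were marked over 0.674% ± 0.10 (SD, n = 2) and U over 1.22% ± 0.0285, and Uextra held 0 regions. Regions on XHet appeared only in the combined list, and the regions of the replicates on YHet shared no base. Much of this sequence is repetitive, and reads from repeats can be lost in alignment, so a low share there does not show absence of the mark.

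**Figure D2:**
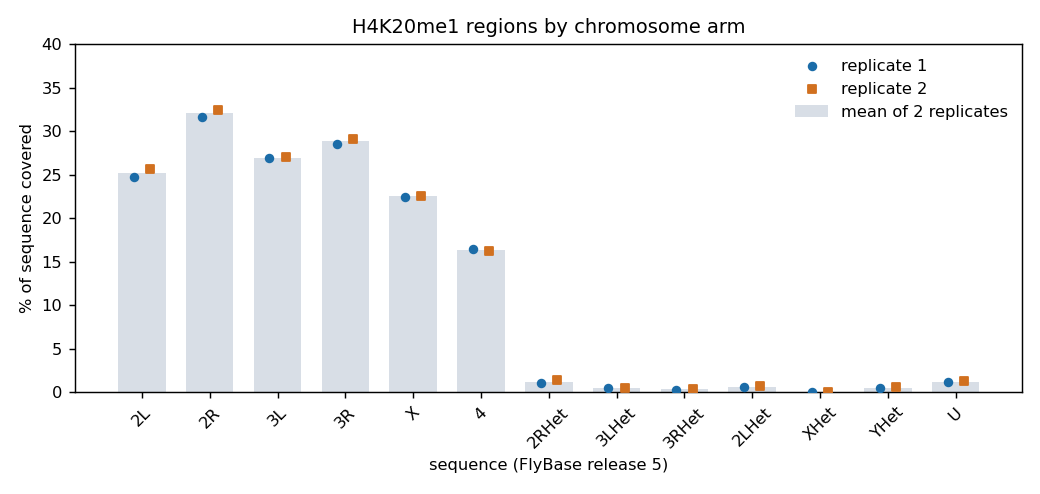
Percentage of each sequence covered by H4K20me1 regions, with bars for the mean of the 2 replicates and points for each replicate (circles, replicate 1; squares, replicate 2). Arm 2R is highest at 32.0%, X stands at 22.5% and chromosome 4 at 16.3%, and the heterochromatic and unplaced sequences lie near 0.

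A smaller share of the X chromosome than of the autosomal arms lay inside called H4K20me1 regions. Coverage does not measure the amount of the mark. Windows of 500 kb were marked in both replicates over 20.3% of their length on X and 26.1% on 2L, 2R, 3L and 3R. The difference was -5.79 percentage points (permutation p = 0.00431, 45 against 193 windows). Per replicate, coverage was 22.4% of X and 27.9% of the autosomal arms in replicate 1, and 22.5% and 28.5% in replicate 2. The call was lost when the dependence of neighbouring positions was kept by rotating the joined arms (-5.70 percentage points, permutation p = 0.111). X is a single stretch of the genome, and chance placement was not excluded. The rotations include small shifts that leave X nearly in place, so they can miss a difference. The lack of a call therefore does not show that X is like other stretches of that length.

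X was also covered less by strong regions, here those of score 1.5 or more, and by wide regions. Regions of score 1.5 or more in the combined list covered 3.62% of X, against 6.71% of 2L, 7.54% of 3L, 8.11% of 3R and 10.98% of 2R, a ratio of X to autosomes of 0.439 and a difference of -4.66 percentage points over windows. The ratio was 0.482 in replicate 1 and 0.490 in replicate 2, compared with 0.805 and 0.792 over all their regions. The change of the ratio with score was not tested. Counted over bases of the combined list, the difference was -4.64 percentage points for regions of score 1.5 or more. For regions of score 1 or more it was smaller, at -3.78, so regions between these bounds did not cover X less. Scores spanned a narrower range on X. In replicate 1 the tenth percentile was 0.54 on X and 0.45 on the autosomal arms, and the ninetieth percentiles were 1.49 and 1.62. The median score was higher on X in all 3 lists, at 0.83 against 0.78 in replicate 1, 0.81 against 0.77 in replicate 2 and 0.573 against 0.565 in the combined list. These bounds and classes were chosen after seeing the data.

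Wide regions covered 4.14% of X and 6.94% of the autosomal arms in replicate 1, and 4.06% and 7.30% in replicate 2, differences of -2.82 and -3.28 percentage points over windows. Over the 6 comparisons of strong or wide regions, adjusted permutation p over windows was between 0.000840 and 0.0256. By rotation, the wide regions kept the call in each replicate (adjusted permutation p = 0.0195 in both) and lost it in the combined list (adjusted permutation p = 0.0638). The strong regions lost it in all 3 lists (adjusted permutation p = 0.0953 in each).

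**Figure D3:**
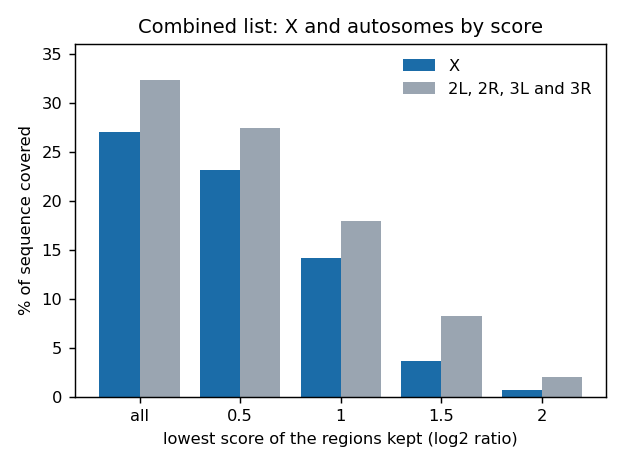
Percentage of X and of the 4 large autosomal arms covered by regions of the combined list (vertical axis) as regions of lower score (log2 ratio) are left out (horizontal axis). The ratio of X to autosomes is 0.836 over all regions, 0.844 from a score of 0.5, 0.789 from a score of 1 and 0.439 from a score of 1.5.

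Coverage varied from window to window along each arm, and the densest 500 kb window was the same in both replicates. It was on 2R from 17000001 to 17500000, marked over 63.9% in replicate 1 and 67.1% in replicate 2. Other dense windows were on 3R from 19500001 to 20000000, with 56.1% and 59.1%, and on 2R from 11500001 to 12000000, with 58.2% and 58.8%. Among the emptiest were the window on 3L from 23500001 to 24000000, with 0% in both, and the one on 2L from 22500001 to 23000000, with 0.366% and 0.355%.

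**Figure D4:**
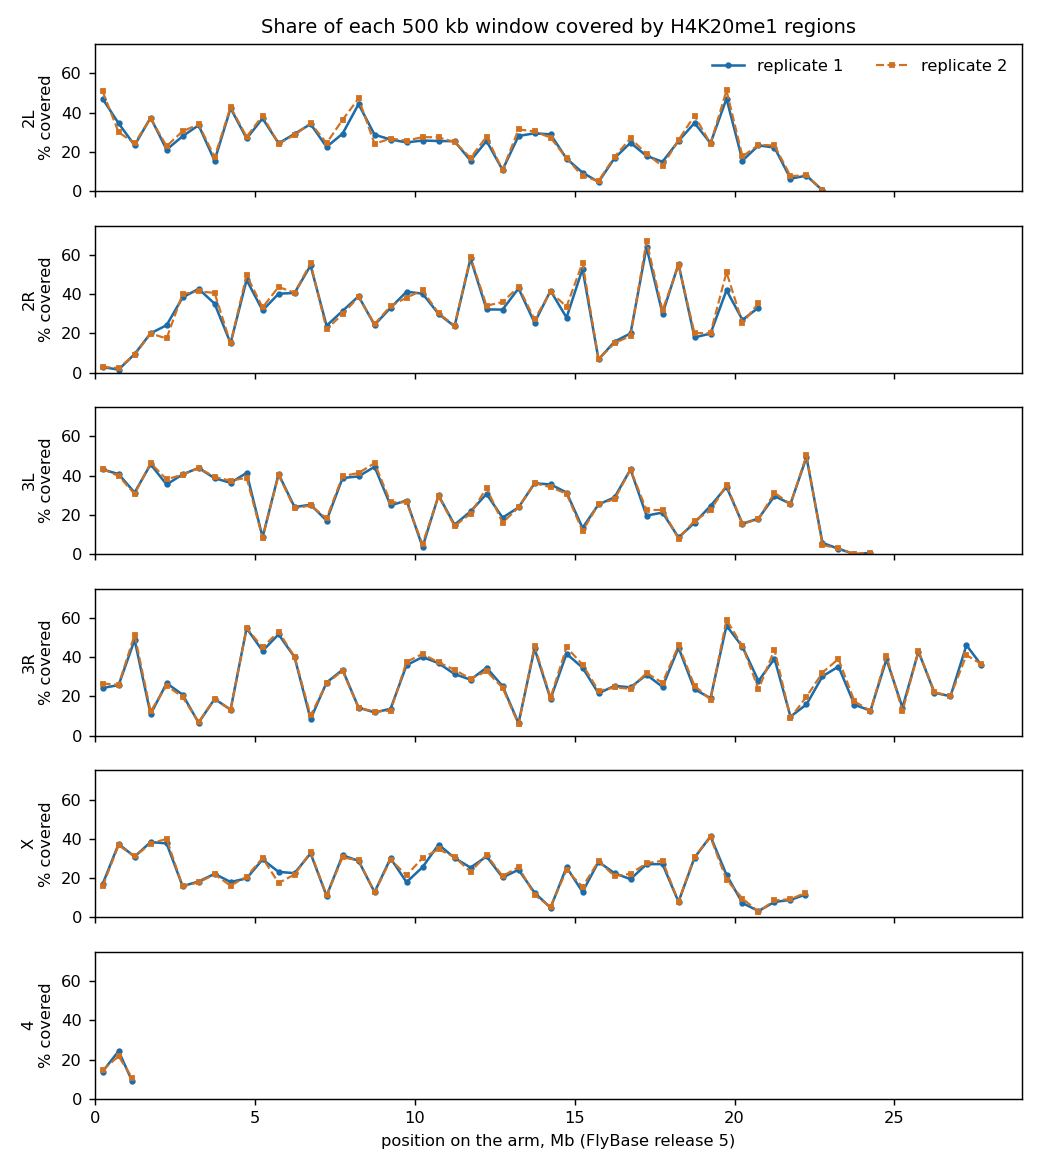
Percentage of each 500 kb window covered by H4K20me1 regions (vertical axes) along the 5 large arms and chromosome 4 (horizontal axis, Mb), with circles and a solid line for replicate 1 and squares and a dashed line for replicate 2. The highest window of both replicates is on 2R from 17000001 to 17500000, with 63.9% and 67.1%.

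The 5 widest regions of the combined list were on chromosome 3. On 2R the widest region was 102597 bp in that list, and 100431 and 100584 bp in the replicates. The combined list's widest, on 3L from 441995 to 576471 (134 kb, score 1.79), was split into 2 regions in replicate 1 and 4 in replicate 2, which covered 99.4% and 97.4% of it. On 3R, the region from 5698729 to 5816872 (118 kb, score 2.59, a 6.02-fold ratio) was a single region in both replicates, with scores of 2.55 and 2.63 and a width of 117.5 kb ± 1.09 (SD, n = 2). Toward the centromere end of 3L, but outside its last 2 Mb, lay 2 more. One ran from 22287216 to 22401614 (114 kb, score 2.53, a 5.78-fold ratio) and was found as 1 region of 114 kb in each replicate, with scores of 2.52 and 2.54. The other ran from 22128629 to 22235261 (107 kb, score 1.06) and appeared as 4 regions in replicate 1 and 3 in replicate 2. The fifth was on 3R from 15317723 to 15420891 (103 kb, score 1.35), made of 3 regions in each replicate.

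Of the 5 regions with the highest scores, 4 were short and on U. They ran from 8776715 to 8780111 (score 3.24), from 9205116 to 9208096 (3.20), from 7843133 to 7846515 (3.17) and from 7585563 to 7586569 (3.17). The last was 1007 bp wide, below the smallest width of 1301 bp in the replicate lists, and was in neither of them. The remaining one, on 2R from 8803071 to 8811593, was 8523 bp wide with a score of 3.20, a 9.21-fold ratio, and scored 3.25 and 3.20 in the replicates.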

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

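The removal of the centromere ends, the pairs of arms, and the comparisons of strong, wide and named regions were chosen after seeing the data, and the bound of score 1 after the lists were read but before its result was seen. X stayed below the autosomal arms under all 8 alternatives, from -6.02 to -3.87 percentage points, with permutation p under 0.05 in 7. Those 7 all permuted windows as exchangeable, so they do not address the dependence of neighbouring windows. Permutation p was 0.00043 with 100 kb windows and 0.011 with 1 Mb windows, at differences of -5.70 and -5.43. With rotation of the joined arms the difference was -5.70 and permutation p was 0.111, and the cause was not tested. Rotation of joined pairs of arms left 0 of the 3 pairs that differed over windows, and the cause was not tested. Leaving out a replicate gave -6.02 to -5.53. The Jaccard index kept its call with a median-score filter (83.5%) and on the 5 large arms and chromosome 4 alone (85.3%). A reciprocal overlap of 50%, a stricter rule by construction, lowered the shared regions to 77.3% in replicate 1 and 77.6% in replicate 2. The median-score filter left 3011, 2997 and 3425 regions in replicate 1, replicate 2 and the combined list, over 25.2, 25.9 and 30.3 Mb. Merging regions less than 1 kb apart lowered the counts to 4304, 4353 and 4606 regions and raised the covered bases to 33.1, 33.7 and 38.7 Mb, since the gaps were added. In the combined list, coverage rose to 29.1% of 2L, 36.7% of 2R, 30.7% of 3L, 33.2% of 3R, 27.0% of X and 19.6% of chromosome 4. A single replicate covers at least the bases common to both, and gave 24.7% to 25.6% of 2L, 31.6% to 32.5% of 2R, 26.9% to 27.0% of 3L, 28.5% to 29.1% of 3R, 22.4% to 22.5% of X and 16.2% to 16.5% of chromosome 4. Widths and scores of the named regions in the replicate lists differed from the combined values by more than the replicate SD in 19 of the values compared and by less in 17. Leaving out regions narrower than 1 kb removed no replicate region, and alternatives concerning genes were not run, for want of an annotation of release 5. No paired analysis was possible because no region list of the input libraries was analysed here. Unknown depth limits the weak regions most.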

Other observations

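The tests of the centromere ends and of the difference split by score were chosen only after their results were seen, as were the positions named here.

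The ends of the arms next to the centromere were poor in H4K20me1 regions, except on 3R. In the last 2 Mb of 3L, 1.92% of bases were marked in both replicates, against 27.1% of the rest of the arm. The corresponding values were 8.18% and 24.5% on 2L, 7.42% and 31.9% on 2R, and 6.60% and 21.7% on X. On 3R the proximal 2 Mb was marked over 26.3%, close to 26.7% for the rest. Reads from repeats can be lost in alignment, and the repeat content of these ends was not examined. A low share there does not show absence of the mark, nor the 3R value a difference in it. At the opposite, telomeric ends, the outermost 2 Mb was marked over 38.1% of 3L, 32.9% of 2L, 28.6% of 3R, 27.5% of X and 26.6% of 2R. On 3L the strongly marked 114 kb region ended at 22401614, and the longest stretch without a region in either replicate, 695 kb, began at 23329677. The 500 kb windows starting at 22500001 and 23000001 were marked in both replicates over 4.42% and 2.60%.

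Some long unmarked stretches lay well inside the arms. On 3L no region of any of the 3 lists fell between 18177588 and 18612179 (435 kb). On X neither replicate had a region between 13724276 and 14102327 (378 kb), and the combined list covered 0.884% of it. On 2L the stretch from 14689923 to 14976369 (286 kb) was empty in all 3 lists.

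Short regions on U had high scores. The 40 regions on U in replicate 1 had a median score of 1.82, against 0.72 in 2293 regions of like width on the large arms, and the 47 in replicate 2 had 1.56 against 0.66. Of regions with a score over 2.5, U held 7 of 45 (15.6%) in replicate 1, 9 of 44 (20.5%) in replicate 2 and 11 of 44 (25.0%) in the combined list. Read counts are not in the lists, so whether these ratios rest on few reads is unknown.

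The low share of X may be set by how regions were called, if reads were fewer on X and weak regions were missed there. The sample titles do not give the sex of the embryos, so the dose of X is not known. The tenth percentile of score was higher on X in all 3 lists, which missed weak regions could give. It was 0.539 against 0.455 on the autosomal arms in replicate 1, 0.526 against 0.455 in replicate 2 and 0.344 against 0.294 in the combined list. In the combined list X differed from the autosomes by -5.29 percentage points, of which -4.64 (95% block bootstrap interval -6.17 to -2.92) lay in regions of score 1.5 or more and -0.654 (-3.63 to 2.66) in the others. Split at a score of 1, -3.78 (-6.62 to -0.245) lay at or above it and -1.51 (-3.39 to 0.355) below. Most of the difference thus lay in the stronger regions by either bound. These intervals resample blocks of 1 Mb. By rotation of the joined arms, the call for regions of score 1.5 or more was lost (adjusted permutation p = 0.0953). The bound of 1.5 was also chosen from these values, so the splits do not decide whether missed weak regions are the whole cause. Whether they add a part stays open, as the ratio of X to autosome coverage at a score of 1 or more, 0.789 (0.646 to 0.984), did not exclude 0.95. Without the 2 Mb nearest each centromere the difference over windows was -5.81 percentage points, against -5.79 with them. The sparse centromere end of X thus did not account for its size in these lists. The permutation p of 0.00311 treats windows as exchangeable, and no rotation was run without these ends. It therefore does not decide whether the remaining difference is beyond chance. Chance placement stays open given the rotation values, and no biological explanation was tested, as the design has no group that bears on X.

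The larger territory of the combined list might come from its lower width minimum, 1001 bp against 1301 bp. Of the added bases, 22.6% lay in regions narrower than any replicate region, which argues against this as the main source. Joint use of both libraries stays open and untested, since how the combined list was made is not given in the sources used here.

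The rise of score with width might come from a score that records the highest value inside a region, since a wider region offers more places for a maximum. Where a combined region spanned several regions of replicate 1, its score was closer to the highest of them than to their width-weighted mean in 16.6% of 715 cases, and in 14.9% of 619 cases for replicate 2. These low shares do not exclude a maximum, because combined scores ran lower, by -0.08 and -0.07 at the median where 1 region matched. With that offset removed, a choice made after seeing the data, the shares were 47.0% and 44.6%, so the explanation cannot be told apart from a score averaged over the region. A caller that extends strong regions further stays open too, and no biological explanation was tested.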
